A study of Homo sapiens with 2 samples.

How the data were processed

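Poly(A) RNA of the human lung carcinoma line A427 was sequenced in 2 libraries, 1 of adherent and 1 of floating, sphere-forming cells. Per the labels' protocols, cells were grown in medium with serum, total RNA was extracted with DNase treatment and libraries were made with a KAPA mRNA kit. Per the submitters' processing notes, the tools were FastQC 0.11.1, STAR 2.5.3a and RSEM 1.3.3 with the genome build hg19. The gene annotation, the settings and the use of strand are not given in the sources used here.

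The authors deposited 2 tables with the same 23686 gene symbols and a column for each library. One holds estimated counts per gene, which the authors deposited without normalization, made with RSEM among the tools per the submitters' processing notes. Column totals differ, and 6.38% of adherent and 6.55% of floating values have decimals. The other holds TPM, which the authors scaled before they deposited it, with columns that sum to 999999 and 1000000. Every column of sample values was used, and each was assigned by its name, which is the sample's title. The tables give no coordinates, and since the annotation in hand was on another build, none are printed.

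Estimated counts were rounded to whole numbers. The totals were 26384670 for adherent and 27148842 for floating cells, with 16277 and 16603 genes having at least 1 read. Libraries were scaled by TMM (trimmed mean of M values) in edgeR 4.0.16 under R 4.3.3. The log2 ratio of floating over adherent was computed on (count + 0.5) per effective library size. Genes of at least 1 CPM in at least one library were kept, 13131 in all. The 95% interval of a ratio is the exact Clopper-Pearson interval conditional on the gene's summed reads. Without molecular identifiers, reads are not independent molecules, so intervals and limits cover counting error only. A gene with 0 reads is given an upper limit of 3 reads. A gene is called higher or lower if it is at least 2-fold apart with an interval that excludes no difference. With 1 library per group, edgeR's test and DESeq2's were not run, and neither an SD nor a p-value is given.

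For each of 43 gene lists, members were matched by symbol or older symbol. With at least 5 members tested, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A percentile under 2.5 or over 97.5 is described as outside the random range. The lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule named the 10 genes at each end, by the interval bound nearest to 0, among genes of at least 10 CPM. It also named up to 4 members of each list outside the random range and up to 2 past the 2-fold rule in other lists. Further named were CTNNB1, AXIN2, LGR5, SOX2, CD44, PROM1, ALDH1A1 and MYC, and the 5 genes of highest TPM per library. Genes outside the rule that make up a small count were chosen after their values were seen, as were those in the closing observations. Some genes that the rule takes are not reported here.

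The calculation was tested on a simulated pair of libraries with the real means and totals, 13087 genes tested and 200 changed, for the comparison of floating with adherent cells. All 50 genes changed 3-fold and all 50 changed 4-fold were called, 22 of 50 changed 2-fold and 0 of 50 changed 1.5-fold. Of 12888 unchanged genes 7 were called, and 95.4% of their intervals held 0. A list of 30 genes shifted by 0.3 (log2) lay at percentile 100, and 3 of 40 unshifted lists fell outside the random range. To set the count of 2-fold genes in context, 20 pairs of libraries with no difference were simulated with counting error alone and with an assumed coefficient of variation between cultures.

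Alternatives were DESeq2 1.42.0 size factors, library totals, the upper quartile, the deposited TPM (log2 of TPM + 0.1, no interval), a prior count of 5, no filter, a minimum of 5 CPM, 1.5-fold and 4-fold thresholds, no counting interval, unmatched random lists and the mean over members. Added after the data were seen were genes with whole-number estimates only and the removal of a trend over effective length (from reads per TPM) or over GC content. GC content came from the longest GENCODE v29 transcript of each symbol, found for 92.3% of tested genes, and length for 98.7%. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.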

Results

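The data hold the poly(A) transcriptome of A427, a human non-small cell lung carcinoma line that grows both attached to the dish and as floating spheres. The series title describes the line as CTNNB1-mutated, CTNNB1 being the gene for beta-catenin, the transcriptional effector of WNT signalling, while the sample labels give its genotype as wild type and name no gene. Attached cells and sphere-forming, floating cells were collected separately, and 1 library was sequenced for each, so the question was which genes differ between the growth forms of one line. The adherent library held 26384670 gene-assigned reads and the floating library 27148842. Of 23686 gene symbols, 13131 reached 1 CPM (counts scaled to library size, per 1000000) in at least one library, about 27 reads in the adherent one, and were compared. There was no replicate of either growth form, so no test across genes was made and no p-value is given. Each fold below compares these 2 libraries, and its 95% interval is an exact binomial interval that covers counting error only, not the spread between cultures. Genes are identified by symbol alone, and no coordinates are given.

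The 2 libraries were alike for most genes. The 5 transcripts with the highest TPM (transcripts per 1000000) were the same genes in both: TMSB10 (thymosin beta-10, which binds actin monomers), RPL41, RPS27, ANXA1 and GAPDH. TMSB10 stood at 12714 TPM in adherent and 14871 TPM in floating cells, a 1.19-fold difference (interval 1.18 to 1.21). The log2 ratio of GAPDH was 0.04 on scaled counts and -0.0004 on TPM. Of the tested genes, 93.3% lay within 1.5-fold. By the rule of at least 2-fold with a counting interval that excludes no difference, 168 genes were higher and 99 lower in the floating library, together 2.03% of those tested. Counts simulated with no difference and with counting error alone put a mean of 10.2 genes past the rule. With an assumed coefficient of variation between cultures of 0.1 the mean was 21.1 genes, and with 0.2 it was 304.9, more than observed. At 0.2 the interquartile range of the log2 ratio was 0.57, against 0.28 in these libraries, over genes of at least 10 CPM. At 0.1 it was 0.29, so that spread with no difference gave about the range seen in these libraries. Of the 267 genes past the rule, 105 passed it with a minimum of 5 CPM. The same coefficient was assumed for all genes, so the ranges do not exclude a spread of 0.2 among less abundant genes.

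**Figure D1:**
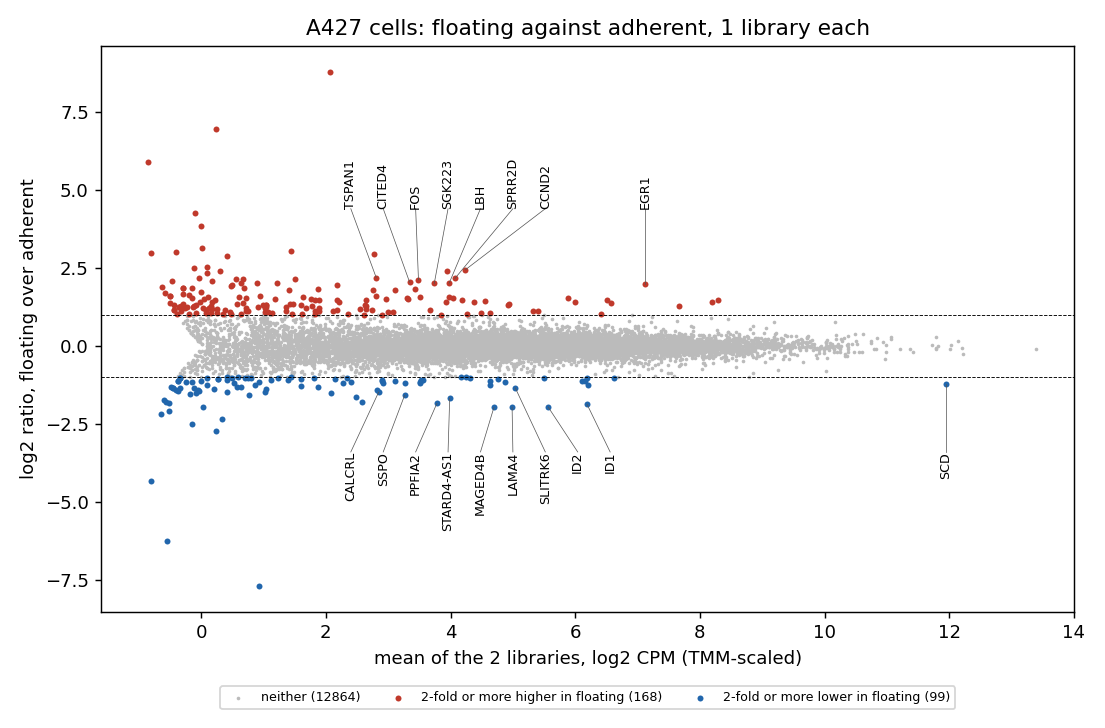
Log2 ratio of floating over adherent A427 cells (vertical axis) against the mean log2 CPM of the 2 libraries (horizontal axis), 1 point per tested gene. Red points are the 168 genes at least 2-fold higher and blue points the 99 at least 2-fold lower in the floating library, dashed lines mark 2-fold, and labels name genes described in the text among the 10 at each end, chosen by the bound of the counting interval nearest to 0.

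Among genes of at least 10 CPM, large excesses in floating cells were in a cyclin, a tetraspanin, a cornified-envelope protein and immediate-early transcription factors. CCND2, which encodes cyclin D2, was 5.43-fold higher (interval 4.59 to 6.51). The tetraspanin TSPAN1 was 4.56-fold, the small proline-rich protein SPRR2D 4.48-fold and the transcription factor FOS 4.34-fold higher. The transcriptional co-regulator CITED4 (4.12-fold), LBH (4.05-fold), SGK223 (4.01-fold) and EGR1 (interval 3.77 to 4.24) were among the 10 genes at this end. EGR1, a zinc finger transcription factor, was at 39.65 TPM in adherent and 153.7 TPM in floating cells. SPRR2D belongs to a family of similar genes that share reads. Summed over that family, the log2 ratio was 1.90.

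At the other end stood inhibitors of basic helix-loop-helix factors, a laminin chain and a lipid desaturase. ID2 was 3.88-fold lower in floating cells (interval 3.52 to 4.28), at 136.2 and 34.1 TPM, and ID1 was 3.66-fold lower (3.39 to 3.95), at 296.1 and 79.3 TPM. LAMA4, a laminin chain of mesenchymal and vascular basement membranes, was 3.89-fold lower (3.46 to 4.39). SCD, the desaturase that makes oleic acid, was 2.35-fold lower (2.33 to 2.38), at 2196 and 904 TPM, and was by far the most abundant gene of this group. PPFIA2, a liprin of synapses, was 3.58-fold, STARD4-AS1 3.18-fold, SSPO 2.99-fold, the receptor CALCRL 2.79-fold and the neuronal membrane protein SLITRK6 2.54-fold lower. MAGED4B was 3.93-fold lower on its own, but it shares reads with the near-identical MAGED4, and for their sum the log2 ratio was -0.57. STARD4-AS1 is an antisense gene, and whether the reads were counted by strand is not given in the sources used here.

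To describe groups of genes, 43 lists were fixed before the data were examined. In 39 of them at least 5 members were measured. The median log2 ratio of each was placed among 10000 random lists of the same size and expression level. Medians of 9 lists lay above and of 9 below the central 95% of the random lists, against 1.95 of 39 expected for unrelated genes. The random lists hold genes drawn independently, so 1.95 does not allow for members that vary together or for overlap between lists. It therefore does not exclude chance. These percentiles describe the 2 libraries and are not p-values. Counting intervals are narrow at this depth, and among all tested genes 25.4% had an interval above 0 and 25.6% one below 0, so member counts below are to be read against those shares. The lists for extracellular matrix, epithelial genes, cell cycle inhibitors, hypoxia, heat shock, focal adhesion and NF-kB came inside the random range under at least one alternative calculation, and those for the WNT pathway, cancer stem cell markers, pluripotency factors, integrins, MAPK feedback, actin and SRF targets, matrix remodelling, interferon response, lung lineage and ABC transporters came outside it. Lists overlap, with ATF3, STC2 and collagens each in more than one.

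**Figure D2:**
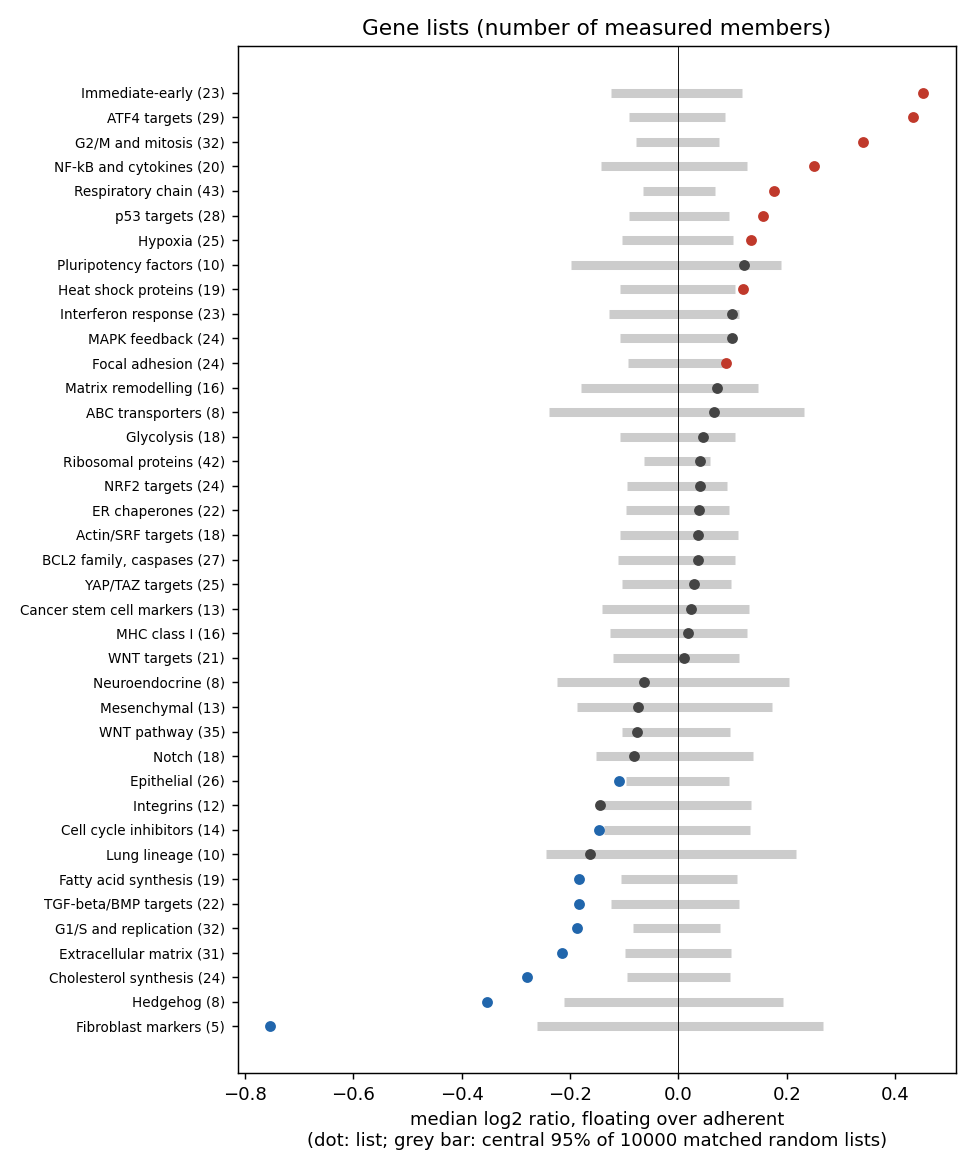
Median log2 ratio of floating over adherent cells (horizontal axis) for the 39 gene lists with at least 5 measured members (vertical axis, number of members in brackets). Dots are the lists, red above and blue below the grey bar, which spans the central 95% of 10000 random lists matched on expression. Immediate-early genes are highest at 0.45, and fibroblast markers lowest at -0.75.

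The labels and title point to WNT signalling and stem cell properties. CTNNB1 itself was 1.13-fold lower in floating cells (interval 1.10 to 1.16), at 279 TPM in adherent and 240 TPM in floating cells. The WNT target list showed no common direction. None of its 21 measured members passed the 2-fold rule, the median log2 ratio was 0.01 and the mean -0.03, and the list lay at percentile 60.7 of matched lists. AXIN2, a negative-feedback target of beta-catenin, was abundant in both libraries and 1.36-fold lower in floating cells (1.32 to 1.40), whereas MYC was higher, with a log2 ratio of 0.38 (0.31 to 0.45). LGR5, a stem cell marker and WNT target, had 0 reads in both libraries, which allows up to 0.114 CPM in the adherent and 0.1105 CPM in the floating library. Ligands, receptors and core components of the pathway had a median of -0.08 (percentile 7.2), with none of 35 past the rule. Among members of at least 5 CPM that median was -0.12, outside the random range (percentile 0.81).

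Stem cell markers went both ways. Of 13 measured cancer stem cell markers, 2 were at least 2-fold higher and none lower in floating cells, and their median of 0.02 lay within the random range, while their mean of 0.21 lay above it (percentile 99.1). The drug efflux pump ABCG2 was 2.68-fold higher (interval 2.02 to 3.63), with 66 and 184 reads, and the ectonucleotidase NT5E (CD73) 2.16-fold higher (1.98 to 2.37). ALDH1A1, an aldehyde dehydrogenase used to mark stem-like cells, was among the most abundant transcripts and was 1.20-fold lower in floating cells (1.19 to 1.21), at 5015 and 4064 TPM. CD44 (11 and 23 reads) and PROM1 (3 and 2 reads) were near the limit of detection, and the counting intervals of both ratios included no difference. Of 10 measured pluripotency factors, SOX2 was 2.44-fold (1.77 to 3.45) and KLF4 2.06-fold (1.18 to 3.80) higher, both at low levels, but KLF4 missed 2-fold on TPM (log2 ratio 0.91) and with a prior count of 5 (0.89). SOX2 was at 1.79 TPM in adherent and 4.27 TPM in floating cells, and the list's median of 0.12 lay within the random range (percentile 90.9). Its mean of 0.38 lay above it (percentile 98.6), and its median was -0.01 with no filter and -0.02 with at least 5 CPM.

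Hedgehog pathway genes and ID genes were lower in floating cells. All 8 measured genes of the Hedgehog pathway had ratios below 0, 6 of them with counting intervals below 0, and the median log2 ratio was -0.35 (percentile 0.04), or -0.23 with no filter (percentile 1.91). The pathway's targets PTCH1 and GLI1 were 1.45-fold (log2 interval -0.69 to -0.38) and 1.40-fold (log2 interval -0.63 to -0.34) lower, and the transducer SMO 1.26-fold lower, so none passed 2-fold. In the Notch list the target genes HES1 (2.01-fold) and HEY1 (2.01-fold) were lower past the rule, and the other 16 measured members were not past it (percentile 14.9 for the list). HEY1, with 47 and 24 reads, missed 2-fold under 4 of 5 alternatives, with log2 ratios from -0.9963 to -0.8915. The list of TGF-beta and BMP targets also holds ligands such as BMP4 and TGFB1 and receptors such as TGFBR1 and TGFBR2. Its median was -0.18 (percentile 0.21), with 5 of 22 members lower and 1 higher past the 2-fold rule. The 5 were ID1, ID2, ID3, ID4 and SMAD6, which are targets of BMP signalling. ID3 was 2.19-fold lower (2.05 to 2.35), ID4 5.72-fold lower with 41 and 7 reads (log2 ratio at most -1.43), and SMAD6 2.24-fold lower. Other members of the list went both ways, with PMEPA1 1.97-fold higher (1.81 to 2.15) and SKIL 1.55-fold lower (1.47 to 1.62). The 5 lower genes therefore do not describe the targets of TGF-beta.

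Immediate-early genes and several inflammatory genes were higher in floating cells. Of 23 immediate-early genes, 5 were at least 2-fold higher (FOS, EGR1, FOSB, IER3 and ATF3) and none at least 2-fold lower. The median log2 ratio of 0.45 exceeded that of all random lists (percentile 100). JUND (1.22-fold), KLF10 (1.15-fold) and NR4A2 (1.11-fold) were lower, with counting intervals below 0. IER3 was 2.09-fold higher (interval 1.87 to 2.36) and ATF3 2.03-fold higher (1.78 to 2.32), with a log2 ratio of 0.99 on TPM, just short of 2-fold. Of 20 cytokine and NF-kB target genes, 6 were at least 2-fold higher and none at least 2-fold lower (median 0.25, percentile 99.98). Counting intervals lay above 0 for 10 of them and below 0 for 3. The 3 were NFKBIA (log2 ratio -0.26), TNFAIP2 (-0.19) and NFKB1 (-0.09). BIRC3, ICAM1, NFKB2 and RELB had log2 ratios above 0 but of at most 0.05. IL8, a neutrophil chemokine, was 3.58-fold higher (2.56 to 5.21), the chemokine CCL20 2.86-fold higher (2.36 to 3.52), and TNFAIP3, a negative-feedback regulator of NF-kB, 2.90-fold higher (2.49 to 3.40). LCN2 was 5.74-fold higher (2.84 to 14.8), with 8 and 50 reads. The NF-kB list's median was 0.05 with a minimum of 5 CPM, 0.09 with the length trend removed and 0.11 with the GC trend removed, each inside the random range. Among MAPK feedback genes, DUSP5, an ERK phosphatase, was 2.80-fold higher (2.43 to 3.25), with the list at percentile 97.1 and its mean of 0.23 above the random range (percentile 99.5). The MAPK feedback list split, with 12 of 24 counting intervals above 0 and 9 below. The 9 were DUSP6, SPRY2, SPRY4, SPRED1, SPRED2, SPRED3, ETV1, ETV5 and CCND1, with log2 ratios from -0.48 to -0.15.

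Some lists of stress-response genes followed in the same direction. Of 29 measured ATF4 targets, which respond to amino acid shortage and endoplasmic reticulum stress, 24 had counting intervals above 0 and 1 below (median 0.43, percentile 100). Past the 2-fold rule were CHAC1, a glutathione-degrading enzyme (2.76-fold, interval 2.16 to 3.57), the hormone STC2 (2.49-fold, 2.24 to 2.79), SESN2 (2.17-fold, 1.98 to 2.38) and ATF3. Of 28 direct p53 targets, 2 were higher past the rule, 20 had intervals above 0 and 4 below (median 0.16, percentile 99.9). The 4 were TP53INP1 (log2 ratio -0.44), TP53INP2 (-0.26), SERTAD1 (-0.22) and XPC (-0.09). The intervals of MDM2 (log2 ratio -0.002), DDB2, TP53I3 and BBC3 included 0. GDF15, a stress-induced cytokine, was 2.98-fold higher (2.55 to 3.51), and CDKN1A, the p21 inhibitor gene, 1.43-fold higher (1.34 to 1.51). The hypoxia list had a median of 0.13 (percentile 99.5), led by STC2 and by HK2 (1.70-fold). The heat shock list had a median of 0.12 (percentile 98.7), with HSPD1 1.32-fold and HSP90AA1 1.21-fold higher. In that list HSPA1A was only 1.05-fold higher, and HSPA1B and DNAJB1 were 1.08-fold and 1.06-fold lower. Among BCL2-family and caspase genes, the anti-apoptotic BCL2A1, whose estimate has decimals, was 2.64-fold higher (2.26 to 3.10). The caspase CASP10 was 2.67-fold higher with 16 and 45 reads, and the pro-apoptotic BMF 3.50-fold lower (2.70 to 4.64). Other members went both ways, with the pro-apoptotic PMAIP1 1.87-fold and BIK 1.84-fold higher and APAF1 1.19-fold lower. The list as a whole lay at percentile 76.2. Chaperones of the endoplasmic reticulum (percentile 80.0) and NRF2 targets (79.5) lay within the random range.

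**Figure D3:**
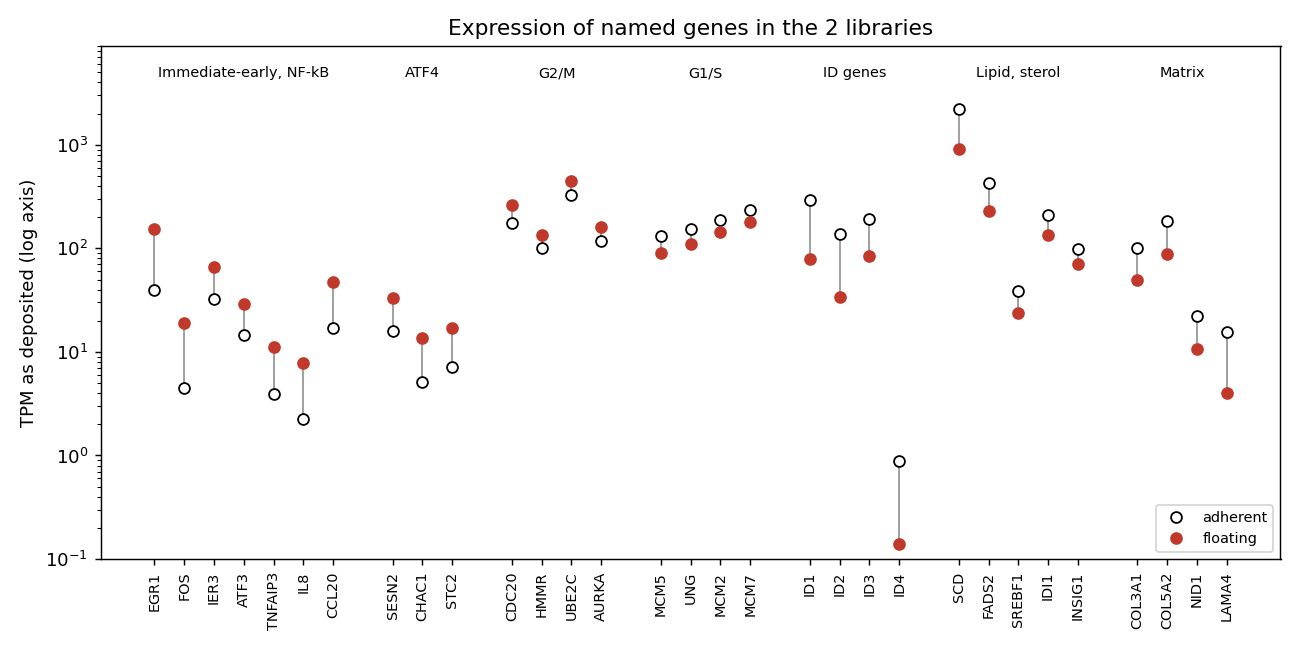
Deposited TPM (vertical log axis) of named genes in the adherent (open circles) and floating (filled circles) library, grouped along the horizontal axis by gene list, 1 value per gene and library. EGR1 stands at 39.65 and 153.7 TPM, ID1 at 296.1 and 79.3 TPM and SCD at 2196 and 904 TPM in adherent and floating cells.

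Genes of the cell cycle differed in opposite directions by phase. All 32 measured genes of G2/M and mitosis had ratios above 0, 30 with counting intervals above 0 (median 0.34, percentile 100). CDC20, an activator of the anaphase-promoting complex, was 1.54-fold higher (interval 1.47 to 1.61), UBE2C 1.41-fold, AURKA 1.40-fold and HMMR 1.40-fold higher. Of 32 genes of G1/S and DNA replication, 23 had intervals below 0 and 2 above (median -0.19, percentile 0.01). The helicase subunits MCM5, MCM2 and MCM7 were 1.42-fold, 1.27-fold and 1.27-fold lower, and the uracil glycosylase UNG 1.36-fold lower. No gene of either list passed 2-fold. Cell cycle inhibitors had a median of -0.15 (percentile 1.83), with CDKN2C 1.32-fold and CDKN1B 1.19-fold lower, but a mean of -0.05 that lay inside the random range. The measured member farthest from 0 was CDKN1A, which was higher, and KLF2 was 1.37-fold higher.

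Lipid synthesis genes were lower and respiratory chain genes slightly higher in floating cells. All 24 measured genes of cholesterol synthesis and uptake had ratios below 0, 21 with intervals below 0 (median -0.28, below all random lists). IDI1 was 1.49-fold lower (interval 1.43 to 1.55), MVD 1.40-fold, LSS 1.38-fold and the sterol sensor INSIG1 1.37-fold lower. Fatty acid synthesis genes had a median of -0.18 (percentile 0.04), with SCD past the rule, FADS2 1.81-fold lower (1.77 to 1.86), the transcription factor SREBF1 1.57-fold lower (1.47 to 1.68) and FADS1 1.38-fold lower. Of 43 nuclear-encoded subunits of the respiratory chain and ATP synthase, 35 had intervals above 0 and 2 below (median 0.18, percentile 100), with NDUFB3 1.46-fold and UQCRB 1.37-fold higher. With the trend over gene length removed, the median of this list was 0.09 and still outside the random range (percentile 99.1). Glycolytic enzymes lay within the random range (percentile 82.7), as did ribosomal proteins (percentile 92.0). The 13 protein-coding transcripts of the mitochondrial genome were not analysed here.

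Matrix and adhesion genes split. Of 31 extracellular matrix genes, 19 had intervals below 0 and 7 above (median -0.21, percentile 0.01), and past the 2-fold rule there were 3 on each side. Lower were LAMA4, POSTN and the basement membrane protein NID1 (2.02-fold, interval 1.86 to 2.20). The fibrillar collagens COL5A2 (1.99-fold, 1.94 to 2.05) and COL3A1 (1.97-fold, 1.89 to 2.05) lay just short of it and passed 2-fold on TPM, while POSTN missed it with a prior count of 5 (log2 ratio -0.92). Among the higher were the laminin chain LAMB3 (3.18-fold, 0.21 and 0.65 TPM) and the proteoglycan VCAN (2.77-fold, 36.1 and 96.9 TPM). Integrins lay at percentile 2.59, with a median of -0.14 and a mean of 0.001, but with no filter the median was 0.22, above the random range (percentile 99.6). The integrins added without the filter had at most 25 reads in either library, and all their counting intervals included no difference. ITGA2, a subunit of a collagen receptor, was 2.66-fold higher (2.57 to 2.75), at 43.9 and 113.1 TPM, and ITGB8 2.01-fold lower (1.76 to 2.31), just short of 2-fold with a prior count of 5. Focal adhesion genes had a median of 0.09 (percentile 97.9), with the adaptors PXN 1.56-fold and BCAR1 1.57-fold higher. In that list TNS1 (1.24-fold), SRC (1.18-fold), VASP (1.13-fold), TLN1 (1.12-fold), VCL (1.10-fold) and FERMT2 (1.08-fold) were lower, with intervals below 0. The SRF target FHL2 was 2.94-fold higher (2.45 to 3.56). YAP/TAZ targets, including NT5E, had a median of 0.03 (percentile 75.2).

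Epithelial genes were slightly lower and mesenchymal genes showed no common direction. Of 26 epithelial genes, 17 had intervals below 0 and 5 above (median -0.11, percentile 1.32), with the junction genes JUP 1.34-fold and CDH1 1.31-fold lower. The list's mean of -0.06 lay inside the random range, and its keratins KRT8 and KRT18, named after their values were seen, were 1.83-fold and 1.84-fold higher. Of 13 mesenchymal genes none passed the rule (percentile 21.4). Fibroblast markers had a median of -0.75 (below all random lists), or -0.33 with no filter (percentile 0.96), but only 5 of 13 were measured, and the list shares COL3A1, COL1A1 and POSTN with the matrix list. COL1A2, DCN, LUM, PDGFRA and PDGFRB, abundant in fibroblasts, had at most 13 reads in either library. Of 20 blood cell markers 4 were measured, with ITGAM 3.64-fold higher (10 and 39 reads), and of 12 endothelial markers 2, with VWF 2.97-fold higher (14 and 44 reads). Within the random range lay the lists for lung lineage (percentile 9.61), neuroendocrine genes (30.8), interferon response (95.8), MHC class I (61.8), actin and SRF targets (73.55), matrix remodelling (85.5) and ABC transporters (74.1). Of these, lung lineage (percentile 0.8) and ABC transporters (97.6) lay outside it with at least 5 CPM, interferon response (97.95) and matrix remodelling (99.3) with no filter, and matrix remodelling (98.1) and actin and SRF targets (98.5) as a mean. Of 27 liver and gut genes 4 were measured, and none passed the rule.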

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

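The whole-number estimates and the length and GC trends were chosen after the data were seen, and the other alternatives before. The lists for immediate-early genes, ATF4 targets, G2/M, respiratory chain, p53 targets, cholesterol, fatty acid synthesis, G1/S, TGF-beta and BMP targets, Hedgehog and fibroblast markers stayed outside the random range under every alternative run, except that fibroblast markers had too few members of at least 5 CPM for a value. Of these, some medians (log2) moved by over 1.5 times: with no filter fibroblast markers (-0.3348) and Hedgehog (-0.2299), with the length trend removed the respiratory chain (0.0908), and as a mean p53 targets (0.2449) and TGF-beta and BMP targets (-0.2778). So did, still outside the range, NF-kB with no filter (0.3829) and as a mean (0.6074), and on TPM focal adhesion (0.0446), hypoxia (0.0795) and heat shock (0.0746). On TPM the median of all genes was -0.0473. With no filter, 286 genes were higher and 164 lower, with at least 5 CPM 64 and 41, at 1.5-fold 426 and 381, and at 4-fold 32 and 8. Fewer or more genes tested, or another threshold, account for these by construction. The share of higher genes was 62.9% in the main calculation, 52.8% at 1.5-fold and 80.0% at 4-fold. Among the lists outside the random range, other medians (log2) came inside the random range, and the cause was not tested. With no filter these were focal adhesion (0.0899), extracellular matrix (-0.0741) and hypoxia (0.0877), and with at least 5 CPM heat shock (0.094) and NF-kB (0.0458). With the length trend removed they were focal adhesion (0.0675), cell cycle inhibitors (-0.1105), heat shock (0.1028) and NF-kB (0.0944), and with the GC trend removed NF-kB (0.1068). Against unmatched random lists they were focal adhesion (0.0888), epithelial genes (-0.1093), cell cycle inhibitors (-0.1474) and heat shock (0.1185). As a mean over members they were extracellular matrix (-0.1259), epithelial genes (-0.0623) and cell cycle inhibitors (-0.0469). Lists inside the random range came outside it as follows, and the cause was not tested. With no filter integrins took the other sign (0.2169, against -0.1439), and matrix remodelling (0.2638) and interferon response (0.136) came above the range. With at least 5 CPM the WNT pathway (-0.1249) and lung lineage (-0.3045) came below and ABC transporters (0.2181) above. As a mean over members, cancer stem cell markers (0.2061), pluripotency factors (0.375), actin and SRF targets (0.1487), matrix remodelling (0.3126) and MAPK feedback (0.2341) came above, the last also with the GC trend removed (0.1049). The log2 ratio of GAPDH was 0.04 on scaled counts and -0.0004 on TPM, the only named gene to take the other sign among those whose counting interval excluded 0. The median of all genes moved the same way, from -0.0048 to -0.0473, so this change goes with the scaling rather than with GAPDH. For 28 other values of named genes, of 760, an alternative lay outside the counting interval. Among genes named here, the 2-fold call was lost on TPM for ABCC6, ATF3, KLF4, HEY1, S100A2 and SPATA18. With a prior count of 5 it was lost for KLF4, HEY1, S100A2, SPATA18, ITGB8 and POSTN, and with DESeq2 size factors or library totals for HEY1. No paired analysis was possible because there is 1 library per group, and for the same reason no replicate could be left out. At this depth 1 CPM is 27 reads in the adherent and 28 in the floating library.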

Other observations

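All tests in this part, and all genes named in its first 2 paragraphs, were chosen after the values were seen. These genes lie outside the fixed lists and were picked for their ratios, and no gene group was tested on them. The cornified-envelope gene SPRR2A was 3.53-fold higher (counting interval 2.90 to 4.35) in the floating library, the keratin KRT81 4.01-fold (2.36 to 7.59), KPRP 5.61-fold with 7 and 43 reads, and S100A2 2.04-fold, which missed 2-fold on TPM (log2 ratio 0.98). SPRR2A shares reads with its family, so its own value is uncertain. The cytokine gene IL32 was 8.33-fold higher (5.01 to 15.7), with 15 reads in the adherent and 133 in the floating library, IL23A 3.61-fold, IL12A 3.77-fold and the complement component C3 2.54-fold higher (2.28 to 2.84). The osteoblast and mesenchymal transcription factor RUNX2 was 3.84-fold higher (2.81 to 5.40).

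The ephrin receptors EPHA3 and EPHA5 were 6.63-fold (54 and 8 reads) and 2.38-fold lower in the floating library, EPHA5 at 28.6 TPM in adherent and 11.7 TPM in floating cells. The neuregulin receptor ERBB4 was 2.09-fold lower and SLITRK3, like SLITRK6 a membrane protein of neurons, 2.20-fold lower. TNFSF10, the death ligand TRAIL, was 5.08-fold lower with 56 and 11 reads. The collagen COL11A1 was 3.15-fold and the laminin chain LAMA2 2.22-fold lower.

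Of 7 genes more than 16-fold apart, 6 had decimals in their estimates: CT45A4, DYX1C1-CCPG1, ATP6V1G2-DDX39B, TMX2-CTNND1, EIF3CL and FAM156B. Each is a near-identical copy or a read-through model of other genes, so its own value is uncertain. Estimates with decimals made up 9.41% of all tested genes and 12.7% of those past the 2-fold rule. The seventh gene, SRPX2, has whole-number estimates of 2 and 49 reads.

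The G2/M genes were higher and the G1/S genes lower in the floating library. Over most genes the length trend spanned 0.1727 (log2). Both medians stayed outside the random range once it was removed, the nearer one 0.1843 from 0, which argues against gene length as the whole cause. The GC trend spanned 0.0472, too little by itself to give these medians. Its removal could therefore change little, and both stayed outside the random range, the nearer one 0.1997 from 0. A different mix of cell cycle phases in the collected cells may underlie the G2/M and G1/S differences, as a hypothesis. With 1 library per group it was not tested whether that follows from growth form or from this pair of cultures.

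Immediate-early genes respond within minutes to handling, so stress of handling at collection could raise them in one library. Of 8 genes taken as marks of handling, 6 had counting intervals above 0, but 5 of these belong to the immediate-early list itself, so that count says little. Of the 3 outside the list, HSPA1A had an interval above 0 (1 gene) and HSPA1B and DNAJB1 below 0, which are too few genes to decide, and HSPA1A and HSPA1B are near-identical copies. The spread between cultures of the same kind also stays open, since there is 1 library per group, as does a difference that goes with growth form.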
